A study of Arabidopsis thaliana with 32 samples.

How the data were processed

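The 32 libraries were polyadenylated mRNA libraries from *Arabidopsis thaliana*, made with an InviTrap plant RNA kit and an Illumina TruSeq kit, per the labels. They fell into 11 groups in 3 experiments. The knockout experiment held 8 libraries of stage 12 petals: *tcp5*, *tcp5 tcp13 tcp17* and Col0 controls. The overexpression experiment held 6 petal libraries: TCP5 driven by the epidermal ATML1 promoter, with its own Col0 controls. The third experiment held 18 inflorescence libraries: an inducible 35S:TCP5 line and Col0 at 0, 2 and 8 h after induction. The inducer, the induction system and the time of day of collection are not given in the sources used here.

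Per the submitters' processing notes, the authors used FastQC, Bowtie2, Cufflinks and the TAIR10 build; no versions are given. Per the file headers, each deposited table gives FPKM (fragments scaled to transcript length and library depth) with a confidence interval. In every library the 33147 annotated gene entries and the 202 pieces assembled on chromosomes held 0. The measured entries were pieces assembled on transcript sequences, so a gene could have several pieces or none. A piece existed only from about 10 fragments, so a gene with no piece lay below the assembly floor of that library and is described as not assembled. The deposited tables list no value for it, and it entered every test as 0. The floor was higher in shallow libraries. Where a whole group was not assembled its SD was 0, so the adjusted p rests on these zeros and not on measured values.

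Fragments per piece were recovered from the width of each deposited confidence interval, which shrinks with the square root of the count. A gene's value was its recovered fragments, divided by the library's total fragments and by the length of its transcript covered in any library, on the scale of FPKM; it is called FPKM below. This value was chosen after seeing the data, because its spread between replicates was lower than that of the length-weighted mean of the deposited FPKM. The median SD on the log2 scale was 0.263 against 0.303 in *tcp5* petals and 0.116 against 0.153 in the overexpression controls; in the triple mutant it was 0.151 against 0.145. The deposited FPKM stayed as an alternative. A piece was found for 23400 genes in at least 1 library and for 13925 genes in all 32; 9542 genes had a symbol in the reference table, whose assembly is TAIR10.1 and from which symbols alone were taken. Coordinates are the deposited TAIR10 ones, counted from 1.

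Recovered depth was 27.9 to 34.0 M fragments (M, mega) in the knockout controls, 15.6 to 34.0 M in *tcp5* and 26.9 to 29.2 M in the triple mutant. It was 3.90 to 8.93 M in the overexpression controls, 4.37 to 17.6 M in pATML1:TCP5 and 23.6 to 36.3 M in the inflorescences. No 2 libraries of a group were duplicates: over the 31 pairs within groups, the lowest chi-square per gene was 4.83. The strand of the reads is not given in the sources used here, so overlapping genes are called uncertain.

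Comparisons used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the empirical Bayes variance trend, a two-sided Benjamini-Hochberg adjusted p under 0.05, and 1 fit per experiment without a replicate block. Folds are ratios of mean FPKM; log2 changes are on the log2(FPKM + 1) scale, which understates low genes. Genes with at least 1 FPKM in as many libraries as the smallest group were tested (2 libraries for the knockouts, 3 for the other experiments). The p-values measure the spread between samples: the labels do not say that replicates came from separate plants, and they may be technical. The groups, comparisons, test, gene lists and rule for named genes were fixed before the data were examined.

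There were 12 comparisons: 3 among the knockout groups, 1 for overexpression, 35S:TCP5 against Col0 at each of 3 times, 3 differences of that effect between times, and Col0 at 2 and at 8 h against 0 h. Genes were named by rule: TCP5, TCP13, TCP17 and ACS2 always; then, among called genes with a symbol and no overlap between groups, up to 8 with the largest increase and 8 with the largest decrease (4 each in secondary comparisons); then up to 3 called members of each list, smallest adjusted p first. Genes named outside this rule are said to be chosen after their values were seen. List members named as examples without this rule (VGD1, PPME1, SHP2, CBF1, CBF3, SAG12, PPH, NYE1, SWEET9, ATML1), the iron genes and genes known by locus number alone were likewise chosen after their values were seen.

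The 22 lists held 334 genes, of which 9 had no piece in any library: CIN-type TCP factors, class I TCP factors, ethylene biosynthesis, ethylene perception and response, boundary and KNOX/BELL genes, cell cycle, petal growth regulators, expansins and XTHs, auxin response, cytokinin response, jasmonate synthesis and response, floral organ identity, photosynthesis and chlorophyll, flavonoid and anthocyanin, epidermis and cuticle, senescence, early response to touch, wounding and cold, circadian clock, pollen markers, tapetum and anther markers, carpel and ovule markers, and meristem and nectary markers. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Of 72 list calls with the preset correlation, none remained with the estimated one; that p is given beside each list.

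Replicate numbers were checked for pairing by the correlation of deviations from group means. The 35S:TCP5 and Col0 libraries at 8 h were the only groups whose 3 same-numbered pairs all correlated above 0.1 (0.27 to 0.80, each library of 1 of the groups best with its own number, so their blocked count is given too); nothing in the labels says what a number marks. Other alternatives were a pseudocount of 0.1, no filter, no variance trend, median-of-ratios rescaling, fits on the compared groups alone, array weights, and leaving out each library. Alternatives chosen after seeing the data were voom on recovered fragments, the deposited FPKM, removal of a trend with transcript length, genes with a piece in every library, a pollen-level covariate, a block within each time, *tcp5* without replicates 1 and 3, and leaving out genes called with time in Col0.

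The steps were tested on simulated data with 200 genes changed. These were drawn only from genes with a mean well above the filter of 1 FPKM, so recovery of low genes was not measured. Every gene was drawn in every library from its real mean and fitted spread, with independent noise. The test of the steps was written after the comparisons were first run. Of genes changed by 1 log2 unit it recovered 66% for *tcp5*, 47% for the triple mutant, 71.7% for pATML1:TCP5 and 91% for 35S:TCP5 at 8 h. For 2 log2 units these shares were 98%, 89%, 92% and 98%. False calls made up 7.34%, 6.85%, 5.78% and 2.58% of calls. Structure shared between libraries was not simulated, so these shares may not hold for the real data. The runs used 17925, 17939, 15851 and 21010 genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.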

Results

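The series measured mRNA in 32 libraries to ask which genes respond to loss and gain of TCP5, a CIN-type TCP transcription factor, in petals and in inflorescences. Stage 12 petals came from 3 *tcp5* libraries, 2 *tcp5 tcp13 tcp17* libraries and 3 Col0 controls, and separately from 3 pATML1:TCP5 libraries and 3 Col0 controls. Inflorescences of 35S:TCP5 and of Col0 were collected at 0, 2 and 8 h after induction, with 3 libraries each. Values are given as mean ± SD in FPKM. The overexpression controls were the shallowest group, at 3.90 to 8.93 M recovered fragments, and the inflorescences held 23.6 to 36.3 M.

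TCP5 itself (AT5G60970, TAIR10 chromosome 5, 24535570 to 24537047) followed the labels in petals. The 3 knockout controls stood at 4.04, 4.45 and 3.72 FPKM, and no TCP5 piece was assembled in any *tcp5* or triple mutant library (adjusted p = 0.00325 and 0.00256). In pATML1:TCP5 petals it stood at 44.2, 33.2 and 34.6 FPKM against 4.00, 4.80 and 4.70 in the controls, 8.30-fold higher (log2 change 2.79, SE 0.14, adjusted p = 0.00041). In 35S:TCP5 inflorescences it was already high at 0 h, at 19.6, 26.1 and 24.5 FPKM against 1.78, 1.72 and 2.05 in Col0. At 2 h the line stood at 38.4, 26.5 and 22.2 against 2.34, 2.59 and 2.42, and at 8 h at 25.9 ± 1.72 against 1.35 ± 0.28. These were 12.6-fold, 11.9-fold and 19.2-fold differences (adjusted p = 4.07e-08, 2.72e-08 and 6.19e-09). The difference at 8 h did not exceed that at 0 h in the test between times (log2 0.43, adjusted p = 0.996).

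**Figure D1:**
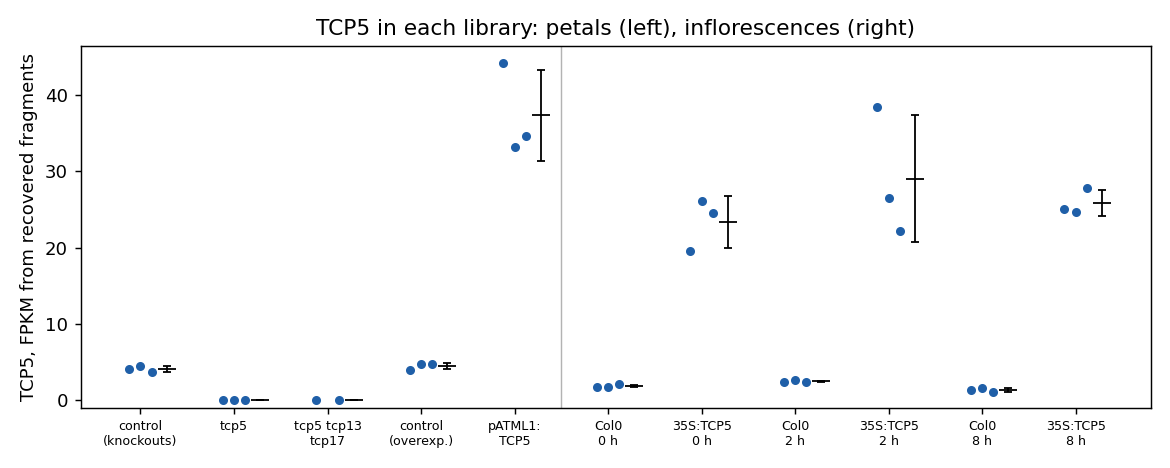
TCP5 level in each library, in FPKM from recovered fragments on the y axis, by group on the x axis; points are libraries and crosses give the mean ± SD. No piece was assembled in *tcp5* or triple mutant petals, and the 35S:TCP5 line stood at 23.4 ± 3.39 FPKM at 0 h.

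TCP13 (AT3G02150, chromosome 3, 391057 to 392758) was at 3.56 ± 0.20 FPKM in control petals (n = 3), 3.29 ± 1.64 in *tcp5* (n = 3) and 1.05 ± 0.17 in the triple mutant (n = 2; adjusted p = 0.238). Its triple mutant pieces covered transcript bases 140 to 515, against 108 to 1347 in the controls. The piece of *tcp5* replicate 3 covered bases 787 to 1300 alone. With the deposited FPKM the triple mutant change of TCP13 turned positive (log2 1.07). TCP17 (AT5G08070, chromosome 5, 2584885 to 2585613) was at 0.536 ± 0.51 FPKM in controls and 2.04 ± 1.23 in the triple mutant (adjusted p = 0.602), with pieces over bases 3 to 714. Transcript level thus did not separate the triple mutant from controls at TCP17; the position of its insertion is not given in the sources used here. ACS2 (AT1G01480), an ethylene synthesis gene, had no piece in most petal libraries.

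A small set of genes was higher in *tcp5* petals. CEP2, a papain-type cysteine protease gene (AT3G48340, chromosome 3, 17897739 to 17899208), rose 7.24-fold, to 15.3 ± 2.41 FPKM from 2.11 ± 0.39 (n = 3 and 3; adjusted p = 0.00325). The xyloglucan endotransglucosylase gene XTH24 (chromosome 4, 14819192 to 14820592) rose 6.87-fold, to 43.1 ± 5.50 from 6.27 ± 3.77 (adjusted p = 0.0334). The sugar transporter and senescence gene SAG29 (chromosome 5, 4181042 to 4183306) rose 1.88-fold, to 13.7 ± 1.63 from 7.33 ± 0.46 (adjusted p = 0.0475).

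Further increases in *tcp5* were UMAMIT20 (9.90-fold, adjusted p = 0.00665), GLYI7 (5.99-fold, adjusted p = 0.0243), EDF1, an ethylene response DNA-binding factor gene (5.54-fold, adjusted p = 0.0474), and the EXORDIUM-like gene EXL4 AT5G09440 (4.08-fold, adjusted p = 0.0279). MRD1 (chromosome 1, 19963047 to 19964712) reached 19.0 ± 2.95 FPKM and MT1B 3.59 ± 1.49, with no piece in the controls (adjusted p = 0.000166 and 0.0167). HEI10, at 6.87 ± 1.07 against 0.222 ± 0.066, overlaps MRD1 and is uncertain. JAZ5, a jasmonate repressor gene, fell to 51.1 ± 3.17 from 91.7 ± 4.40 (log2 change −0.83, adjusted p = 0.0291).

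Of 18281 genes tested, 48 were called in *tcp5*, 44 higher and 4 lower, and 2201 had an unadjusted p under 0.05. Replicate 3 of *tcp5* covered a median of 47.0% of long transcripts, against 97.6 to 97.7% in the controls. Its pieces lay toward the transcript end, with a median midpoint at 74.5% of the length. Without this replicate 50 genes were called, 41 of them among the 48. How far its coverage shaped the calls was not tested. Groups did not overlap for 23.8% of genes, where chance gives 10%. The count was 6, 6 and 8 without control replicates 1, 2 and 3, 74 without *tcp5* replicate 1 and 1181 without *tcp5* replicate 2. With a pollen-level covariate 3 genes were called, and without *tcp5* replicates 1 and 3 there were 54, of which 27 were among the 48; that leaves 1 *tcp5* library, so the other groups alone supply the spread. Lower calls were few here but not under each setting: 175 were higher and 88 lower with the length trend removed, and 261 and 89 with array weights.

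Pollen marker transcripts were high in *tcp5* replicates 1 and 3. VGD1 stood at 713, 68.7 and 232 FPKM in replicates 1, 2 and 3 against 30.9, 26.1 and 45.6 in controls, and the other pollen pectinesterase gene of the list, PPME1, at 599, 27.0 and 237. All 6 pollen markers were higher adjusted over the list alone, none over all genes (median log2 change 2.75, adjusted p = 3.53e-05; adjusted p = 0.370 with an estimated correlation). The tapetum and anther list went the same way, with 4 of 4 higher adjusted over the list alone and none over all genes (adjusted p = 0.00763; adjusted p = 0.413 with an estimated correlation). SHP2, the single carpel and ovule marker tested, was at 5.44 ± 1.3 against 2.72 ± 0.46 (list adjusted p = 0.0787). With 1 gene, adjustment over the list alone leaves the unadjusted limma p, which was under 0.05.

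**Figure D2:**
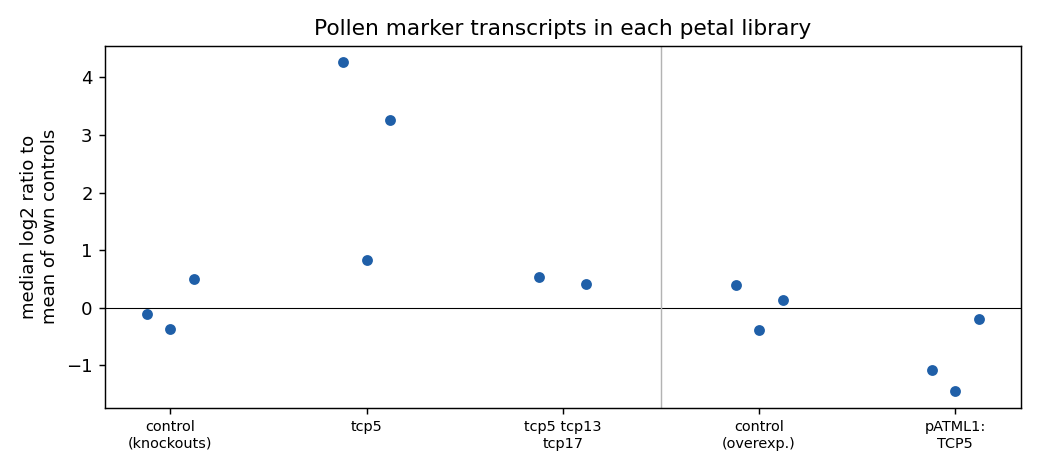
Median log2 ratio of the pollen markers in each petal library (x axis) to the mean of that library's own controls (y axis); points are libraries. It stood at 4.26, 0.82 and 3.26 in *tcp5* replicates 1, 2 and 3 and at 0.54 and 0.41 in the triple mutant.

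Beside these markers, the auxin response list was higher in *tcp5* (median log2 change 0.44, adjusted p = 3.53e-05; adjusted p = 0.370 with an estimated correlation). None of its 24 members was called over all genes, and 10 were higher adjusted over the list alone. Genes of the early response to touch, wounding and cold were lower (median −0.57, adjusted p = 3.53e-05; adjusted p = 0.370 with an estimated correlation), with 0 of 13 called and 8 lower adjusted over the list alone. Among them the cold regulator genes CBF1 and CBF3 stood at 11.4 ± 2.67 against 22.3 ± 2.35 and at 21.5 ± 5.71 against 37.7 ± 3.54. The senescence list was higher (adjusted p = 0.00331; adjusted p = 0.370 with an estimated correlation), with 1 of 10 called and 2 higher adjusted over the list alone; its SAG12 ranged widely, at 37.0 ± 32.9 against none assembled. CIN-type TCP factors were lower (adjusted p = 0.0113, and adjusted p = 0.543 with an estimated correlation), with TCP5 as the 1 call of 8, likewise adjusted over the list alone. TCP5 is the mutated gene, so this result in part restates the genotype, and the list was not tested without it. The cell cycle list had 0 of 19 called, also adjusted over the list alone (adjusted p = 0.193).

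In the triple mutant several of these genes were again called higher than in controls. XTH24 rose 12.3-fold, to 76.9 ± 11.6 FPKM (n = 2 against 3; adjusted p = 0.00998), and CEP2 14.1-fold, to 29.6 ± 4.37 (adjusted p = 0.00131). SAG29 rose 2.80-fold, to 20.5 ± 0.89 (adjusted p = 0.00491). ORE1, a NAC factor gene that promotes senescence (chromosome 5, 15858400 to 15859788), stood at 3.17 ± 0.013 with no piece in controls (adjusted p = 0.0153). MAP18, a microtubule-associated protein gene, rose to 15.4 ± 4.70 from 0.473 ± 0.42, with 1 control at no piece (adjusted p = 0.0315).

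The jasmonate synthesis genes AOC1 and AOC2 rose 4.72-fold and 3.18-fold (adjusted p = 0.0353 and 0.0115). The arginase gene ARGAH2 rose 11.4-fold, ESM1 10.5-fold, GLYI7 8.11-fold, EDF1 7.50-fold and EXL4 AT5G09440 7.12-fold (adjusted p = 0.003, 0.00735, 0.00939, 0.0179 and 0.00596). RNS1, a ribonuclease gene, and the anthocyanin regulator gene PAP1 reached 5.96 ± 0.67 and 1.59 ± 0.05 with no piece in controls (adjusted p = 0.0308 and 0.0448). Lower were the tubulin gene TUB1 (35.9 ± 0.78 against 63.8 ± 3.56, adjusted p = 0.0161), the drought and heat regulator gene DREB2A (6.45 ± 0.72 against 15.7 ± 0.70, adjusted p = 0.0251) and ENODL18 (25.4 ± 2.63 against 48.9 ± 1.33, adjusted p = 0.0305).

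The senescence list was higher in the triple mutant (median log2 change 0.51, adjusted p = 1.08e-05; adjusted p = 0.376 with an estimated correlation), with 2 of 10 called and 4 higher adjusted over the list alone. Of its chlorophyll breakdown genes, PPH stood at 48.7 ± 4.04 against 35.8 ± 0.50 and NYE1 at 156.5 ± 0.43 against 128 ± 7.17, neither called. Photosynthesis genes were higher as a list (adjusted p = 0.0272; adjusted p = 0.932 with an estimated correlation), with 0 of 25 called, also adjusted over the list alone. Auxin response was higher likewise (adjusted p = 0.0272; adjusted p = 0.706 with an estimated correlation), with 0 of 24 called, also adjusted over the list alone. CIN-type TCP factors were lower (adjusted p = 0.0392, and adjusted p = 0.932 with an estimated correlation), with 1 of 8 called and 2 lower adjusted over the list alone. The list holds the mutated genes, so this result in part restates the genotype. The meristem and nectary list had 1 tested gene, SWEET9, at 1.42 ± 0.29 against none assembled (list adjusted p = 0.0272; adjusted p = 0.376 with an estimated correlation), not called over all genes. With 1 gene, adjustment over the list alone leaves the unadjusted limma p, which was under 0.05. Jasmonate genes split (2 of 25 called higher; 4 higher and 2 lower adjusted over the list alone; list adjusted p = 0.528). Pollen markers were not called (median 0.48, adjusted p = 0.867).

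In all, 115 genes were called in the triple mutant, 107 higher and 8 lower, and 1631 had an unadjusted p under 0.05; groups did not overlap for 43.0% of genes, where chance gives 20% for 2 against 3. The count was 32, 37 and 35 without control replicates 1, 2 and 3, and 10 and 12 without triple mutant replicates 1 and 2, where 1 library is left and the other groups supply the spread. It was 66 with the deposited FPKM and 680 with *tcp5* left out of the fit.

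Between the single and the triple mutant, 38 genes were called higher in both, where independent lists of 44 and 107 among 18281 would share 0.258, and 2 were called lower in both (TCP5 and AT2G05914, the latter named after its values were seen). Fold changes correlated across genes (r = 0.55), which are not independent replicates. Unchanged groups simulated against the same controls gave r = 0.45 and 0.01 shared calls on average over 100 draws, with a highest r of 0.48. The covariance was 0.116 against 0.0354 simulated, a difference of 0.0803. The simulated noise was independent between libraries, so structure other than genotype that mutant libraries share was not modelled. Deviations of *tcp5* replicate 3 and triple mutant replicate 2 from their group means correlated at 0.79. These were the knockout libraries with the lowest coverage of long transcripts (47.0% and 91.6%). Such structure may thus add to the shared calls and the covariance. The 3 controls cannot be split into separate sets of 2, so the mutants could not be compared through separate controls.

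Tested directly against *tcp5*, the triple mutant differed in 6 genes, 3 higher and 3 lower, with 1143 at an unadjusted p under 0.05; 5 of the 6 had a group with no piece. MRD1 and its overlapping neighbour HEI10 were not assembled in the triple mutant, against 19.0 ± 2.95 and 6.87 ± 1.07 in *tcp5* (adjusted p = 0.000371 and 0.00419). The knockout controls had no MRD1 piece either, and their HEI10 was low. At both genes *tcp5* was thus the group that stood apart, although the triple mutant lacked TCP5 transcript as well. XTH25 (chromosome 5, 23304888 to 23306421) stood at 2.94 ± 0.09 with no piece in *tcp5* (adjusted p = 0.049). The count was 854 without *tcp5* replicate 2, 9 and 11 without *tcp5* replicates 1 and 3, and 1 without either triple mutant library, which leaves 1 in that group.

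Of the lists, 10 differed between the mutants, and none with an estimated correlation (lowest adjusted p = 0.197 with an estimated correlation). Jasmonate genes were higher in the triple mutant (adjusted p = 1.09e-06), with 0 of 25 called and 4 higher adjusted over the list alone; AOC2 stood at 13.4 ± 0.82 against 4.96 ± 0.81. Pollen markers were lower (median −2.24, adjusted p = 1.09e-06), with 0 of 6 called and 6 lower adjusted over the list alone. Class I TCP factors were higher (adjusted p = 0.0246), with 0 of 10 called, also adjusted over the list alone.

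Flavonol genes were higher in pATML1:TCP5 petals. The same list fell with time in Col0 inflorescences (11 of 13 at 2 h and 9 of 13 at 8 h), and so did the epidermis and auxin response lists at 8 h, while the early response list, lower in pATML1:TCP5, rose (8 of 11 at 8 h). With an estimated correlation these calls were lost (adjusted p = 0.0960 at 2 h and 0.393 at 8 h with an estimated correlation). Whether the hour of collection contributed to any of them in petals was not tested. The photosynthesis list, of which 26 of 27 fell at 8 h, was not called in pATML1:TCP5. FLS1, flavonol synthase (chromosome 5, 2803957 to 2805606), rose 1.89-fold, to 452 ± 8.53 FPKM from 239.6 ± 15.7 (n = 3 and 3; adjusted p = 0.00163). The flavonol glycosyltransferase gene UGT78D1 rose 4.39-fold, from 4.61 ± 1.64 (adjusted p = 0.00293), and the flavonol regulator gene MYB11 to 10.3 ± 1.97 from 1.22 ± 1.07, with 1 control at no piece (adjusted p = 0.0165). F3H rose 2.01-fold (adjusted p = 0.00272), although it overlaps AT3G51238 and is uncertain. Of 11 flavonoid and anthocyanin genes tested, 9 were called higher and none lower, and 10 were higher adjusted over the list alone (median log2 change 1.00, adjusted p = 5.57e-08; adjusted p = 0.319 with an estimated correlation).

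Epidermis and cuticle genes were higher too (median 0.30, adjusted p = 4.81e-05; adjusted p = 0.410 with an estimated correlation), with 6 of 17 called higher and 9 adjusted over the list alone. The wax and cutin regulator gene SHN1 rose 1.65-fold, LACS2, an acyl-CoA synthetase gene of cutin synthesis, 1.72-fold, and MYB16, a petal epidermal cell shape regulator gene, 1.48-fold (adjusted p = 0.0229, 0.0145 and 0.00415). ATML1, whose promoter drove the transgene, stood at 43.7 ± 2.54 against 30.2 ± 4.01 (adjusted p = 0.0267). Auxin response genes were higher (median 0.50, adjusted p = 0.0255; adjusted p = 0.319 with an estimated correlation), with 6 of 22 called higher; adjusted over the list alone 9 were higher and 2 lower. SAUR65 rose 2.09-fold, SAUR68 1.87-fold and IAA2 1.58-fold (adjusted p = 0.00987, 0.0133 and 0.0145).

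Senescence genes were lower in pATML1:TCP5 petals (median −0.45, adjusted p = 6.91e-05; adjusted p = 0.251 with an estimated correlation), with 3 of 7 called lower and 5 adjusted over the list alone. The senescence regulator gene NAP fell to 44.9 ± 4.91 from 79.8 ± 10.9 (adjusted p = 0.00965), SAG29 to 4.32 ± 1.36 (log2 change −1.09, adjusted p = 0.0229) and PAO, a chlorophyll breakdown gene, to 26.3 ± 0.92 from 36.1 ± 2.86 (adjusted p = 0.0229). Pollen markers were lower (median −0.85, adjusted p = 0.0177; adjusted p = 0.561 with an estimated correlation), with 0 of 4 called and 2 lower adjusted over the list alone. Early response genes for touch, wounding and cold were lower (adjusted p = 0.0112; adjusted p = 0.688 with an estimated correlation), with 0 of 13 called, also adjusted over the list alone. CIN-type TCP factors were higher (adjusted p = 0.0376, and adjusted p = 0.561 with an estimated correlation), with TCP5 as the 1 call of 7, likewise adjusted over the list alone. TCP5 is the transgene, so this result in part restates the overexpression, and the list was not tested without it.

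CEP2 fell from 18.2 ± 5.79 FPKM, and was assembled in 1 of 3 pATML1:TCP5 libraries, at 1.21 (adjusted p = 0.00264), so the size of its decrease is not measured. The iron deficiency regulator gene bHLH38 fell from 13.1 ± 7.42, HIPP22 from 9.79 ± 2.19, SEN1 from 11.9 ± 8.93 and MAP18 from 8.19 ± 3.26 (adjusted p = 0.0225, 0.0091, 0.0414 and 0.0197), each assembled in 1 of 3 pATML1:TCP5 libraries. MES1 had no piece, against 5.22 ± 2.03 in controls (adjusted p = 0.0199), and BGAL4 and AIRP2 fell to 3.07 ± 3.05 and 2.18 ± 2.08 (adjusted p = 0.0495 and 0.0338). Among the increases, NEET, TCL1 and CLE16 reached 9.65 ± 1.42, 5.88 ± 0.46 and 5.37 ± 2.56 with no piece in controls (adjusted p = 0.00197, 0.0085 and 0.0201). These controls were the shallowest group, with a high assembly floor, so the size of these increases is not measured. TCL1 encodes a repressor of trichome formation. CRK40, BGLU6 and FMO GS-OX2 rose to 10.2 ± 3.47, 12.4 ± 1.36 and 10.6 ± 2.62, each with 1 control at no piece (adjusted p = 0.0146, 0.0165 and 0.0258).

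The ethylene receptor gene ERS2 fell by 0.58 on the log2 scale (adjusted p = 0.0177), the 1 call of 13 in ethylene perception and response, likewise adjusted over the list alone (list adjusted p = 0.172). Expansins and XTHs split, with 3 higher and 2 lower of 16, and 5 and 3 adjusted over the list alone; the list's median was 0.05 and its mean −0.004 (adjusted p = 0.744). EXPA10, EXPA15 and EXPB3 rose 1.98-fold, 1.55-fold and 1.58-fold (adjusted p = 0.0077, 0.0134 and 0.019), and XTH24 fell to 19.8 ± 2.52 from 64.6 ± 39.6 (adjusted p = 0.0414). Of 13 petal growth regulators 2 were called lower, the cell cycle inhibitor gene KRP1 (log2 change −0.76, adjusted p = 0.0322) and ARL, a promoter of cell expansion (log2 change −0.75, adjusted p = 0.0185); adjusted over the list alone 1 was higher and 3 lower (list adjusted p = 0.122).

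The cytokinin response gene ARR7 rose 2.34-fold (adjusted p = 0.0148), the 1 call of 8, with 3 adjusted over the list alone (list adjusted p = 0.134). The allene oxide cyclase gene AOC3 fell by 0.87 on the log2 scale (adjusted p = 0.0316), the 1 call of 25 jasmonate genes, likewise adjusted over the list alone (list adjusted p = 0.0729). Single calls were also CYCA2;3 of 11 cell cycle genes (2.17-fold higher, adjusted p = 0.0373, but log2 −0.26 with the deposited FPKM), SEP3 of 8 floral organ identity genes (1.24-fold higher, adjusted p = 0.0305) and BLH2 of 6 boundary and KNOX/BELL genes (1.48-fold higher, adjusted p = 0.0268). Adjusted over the list alone these lists had 1, 1 and 2 higher. Among 25 photosynthesis genes CHLH was higher (1.37-fold, adjusted p = 0.0143) and PORB lower (log2 change −0.41, adjusted p = 0.0394); adjusted over the list alone 1 was higher and 3 lower (list adjusted p = 0.172).

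Clock genes with a morning peak were higher in pATML1:TCP5 petals than in their controls, and at CCA1, LHY and RVE8 it was these controls that stood low. In the knockout controls CCA1, LHY and RVE8 were at 14.2 ± 0.66, 22.1 ± 1.17 and 13.1 ± 1.72 FPKM, nearer to pATML1:TCP5 (27.8 ± 5.25 for LHY) than to its controls (5.36 ± 2.28 for LHY). CCA1 (chromosome 2, 19245672 to 19248914) rose 4.57-fold, to 18.1 ± 1.78 from 3.95 ± 0.77 (adjusted p = 0.00154), RVE8 2.98-fold (adjusted p = 0.00264) and PRR9 2.71-fold (adjusted p = 0.00278). PRR9, at 24.9 ± 1.64, stood above both control groups (9.20 ± 1.83 and, for the knockouts, 11.9 ± 0.88). PRR5, which fell (log2 change −1.70, adjusted p = 0.0174), stood at 10.2 ± 5.35, below both (33.4 ± 6.93 and, for the knockouts, 36.6 ± 2.78). Of 13 clock genes, 4 were called higher and 2 lower; adjusted over the list alone 6 were higher and 3 lower. The list's median was −0.13, its mean 0.40 and its test, toward higher, uncalled (adjusted p = 0.683). Genes that fell by 2 or more log2 units in Col0 inflorescences from 0 to 8 h had a median change of 0.47 in pATML1:TCP5 petals (63 genes). Those that rose as much had a median of −0.45 (129 genes), a difference of 0.93 (95% interval over genes, 0.71 to 1.16). Relative to their controls, pATML1:TCP5 petals thus leaned toward the earlier inflorescence time.

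**Figure D3:**
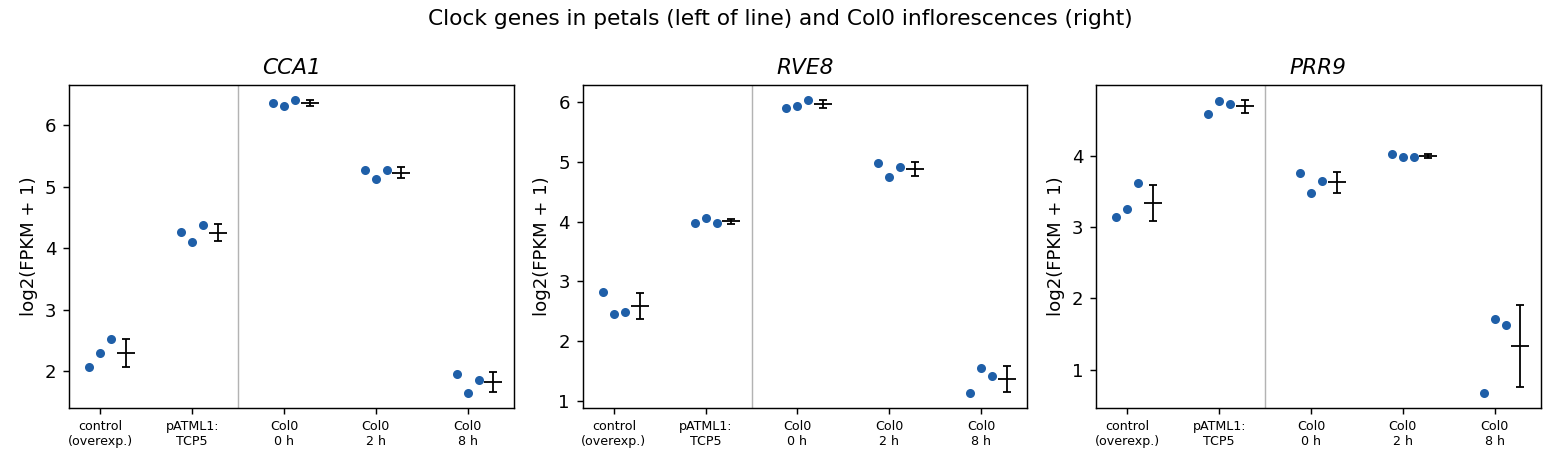
CCA1, RVE8 and PRR9 in each library, as log2(FPKM + 1) on the y axis by group on the x axis; points are libraries, with the mean ± SD. CCA1 stood at 18.1 ± 1.78 FPKM in pATML1:TCP5 petals against 3.95 ± 0.77 in controls, and at 81.4 ± 2.74 at 0 h against 2.55 ± 0.38 at 8 h in Col0 inflorescences.

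Of 16260 genes tested in pATML1:TCP5, 1222 were called, 633 higher and 589 lower, and 4096 had an unadjusted p under 0.05. Groups did not overlap for 32.4% of genes, where chance gives 10%. With median-of-ratios rescaling 36.8% of calls were higher, against 51.8% here. The count was 645, 380 and 813 without control replicates 1, 2 and 3, and 680, 688 and 710 without pATML1:TCP5 replicates 1, 2 and 3. It was 237 with the deposited FPKM, and 248 (120 higher, 128 lower) of 8628 when the 9717 genes called with time in Col0 inflorescences were left out.

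A set of petal genes was called in opposite directions in the mutants and in pATML1:TCP5. Of 33 genes higher in *tcp5* that were also tested in pATML1:TCP5, 19 were called lower there, where independent lists would share 1.18. Of 75 higher in the triple mutant, 35 were called lower in pATML1:TCP5, where 2.69 would be shared. CEP2, XTH24, SAG29, GLYI7 and EXL4 AT5G09440 were among both. So were others chosen after their values were seen: GASA1, a gibberellin-regulated gene (9.81 ± 0.31 in knockout controls, 45.8 ± 0.17 in the triple mutant), and the NAC factor gene NAC047 (3.11 ± 0.27 and 13.3 ± 0.012). Of 7 genes lower in the triple mutant, 2 were called higher in pATML1:TCP5, TCP5 itself and AT3G26450, where 0.273 would be shared. The control groups of the 2 experiments differed at these genes. Over the 36 genes higher in a mutant and lower in pATML1:TCP5, the overexpression controls stood a median of 1.63 log2 units above the knockout controls, about as far as the triple mutant (1.64), and pATML1:TCP5 0.01 above them. The genes were picked by their calls, which favours such a gap, so these medians describe them and test nothing. Called in the same direction in both were ARGAH2, higher, and ENODL18 and TUB1, lower.

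**Figure D4:**
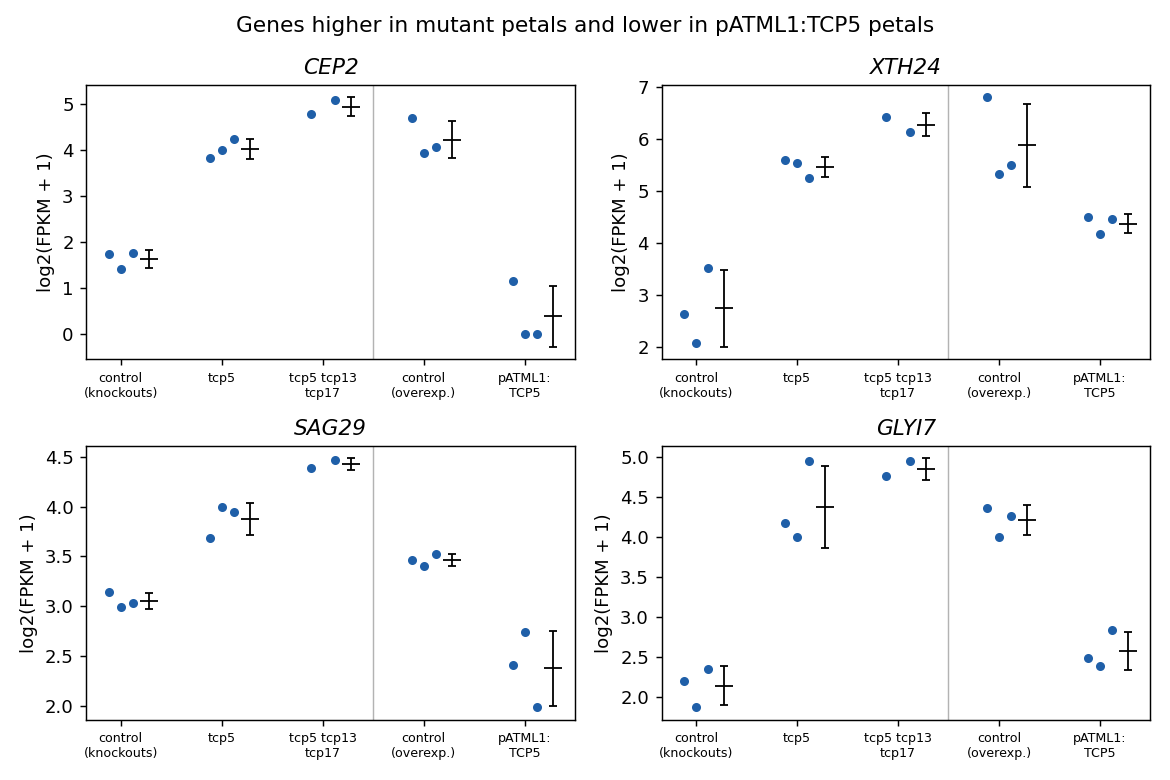
CEP2, XTH24, SAG29 and GLYI7 in each petal library, as log2(FPKM + 1) on the y axis by group on the x axis; points are libraries, with the mean ± SD. Each was higher in both mutants and lower in pATML1:TCP5, as with SAG29 at 20.5 ± 0.89 FPKM in the triple mutant and 4.32 ± 1.36 in pATML1:TCP5.

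As a set, the 582 genes lower in pATML1:TCP5 were higher in *tcp5* (73.7% above 0 against 47.3% of all genes; camera p = 2.77e-14, and p = 0.0263 with an estimated correlation) and in the triple mutant (82.3% against 46.9%; p = 2.42e-27, and p = 0.00674 with an estimated correlation). The 632 genes higher in pATML1:TCP5 were lower in *tcp5* and the triple mutant (p = 0.00456 and 0.00175), but not with an estimated correlation (p = 0.361 and 0.318). Fold changes in pATML1:TCP5 correlated negatively with those in *tcp5* and in the triple mutant across genes, which are not independent replicates (r = −0.38 and −0.38). Pollen markers had the same signs as the genes lower in pATML1:TCP5, with medians of 2.75 in *tcp5*, 0.48 in the triple mutant and −0.85 in pATML1:TCP5. Their sizes did not run together, since the 582 genes shifted by a median of 0.18 in *tcp5* and 0.32 in the triple mutant. With the pollen covariate, 113 of the 115 triple mutant calls were kept, but only 3 of the 48 *tcp5* calls. The median pollen marker stood just 0.54 and 0.41 log2 units above controls in the triple mutant libraries, so the covariate could take little there. In *tcp5* the marker level ran partly with genotype, so neither count settles the share of pollen. How much pollen or anther material contributed to the set was not tested. Opposite calls between the triple mutant and pATML1:TCP5 numbered 9 with the deposited FPKM. Without genes called with time in Col0, 12 of 27 genes higher in the triple mutant were lower in pATML1:TCP5, where 0.392 would be shared.

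**Figure D5:**
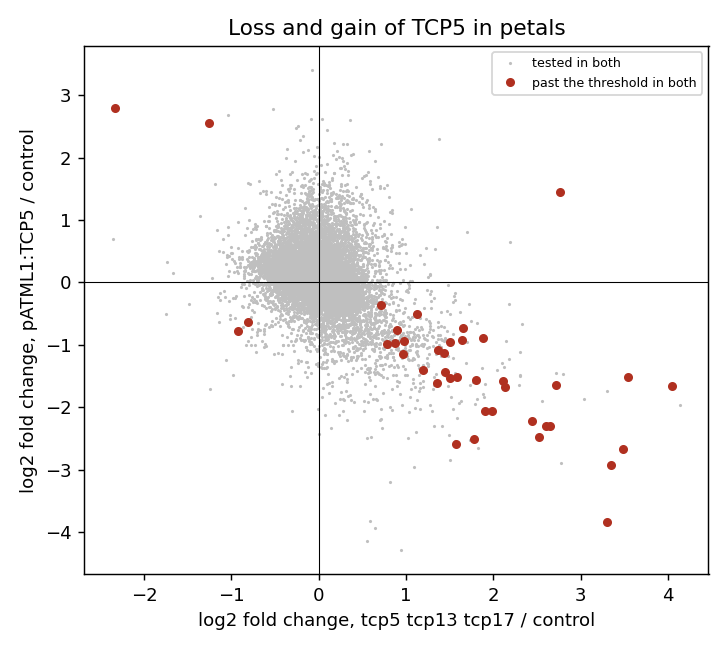
Log2 fold change of each gene in the triple mutant against its controls (x axis) and in pATML1:TCP5 against its controls (y axis); grey points are genes tested in both and red points are those called in both. Of 75 genes called higher in the triple mutant, 35 were called lower in pATML1:TCP5.

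In inflorescences few genes separated 35S:TCP5 from Col0, and 8 of them did so at all 3 times, 0 h included. ZIM, a GATA-type factor gene (AT4G24470, chromosome 4, 12645542 to 12647965), stood at 3.40 ± 0.38 FPKM against 23.6 ± 0.28 at 0 h, and was as low at 2 and 8 h (adjusted p = 6.95e-11, 1.66e-10 and 7.61e-11). NF-YB8, a nuclear factor Y subunit gene, was 2.94-fold, 3.35-fold and 3.33-fold higher at the 3 times (adjusted p = 6.98e-08, 2.47e-08 and 1.84e-08), and its relative NF-YB10 stood at 45.5 against 23.0, 43.8 against 21.7 and 45.2 against 21.8. PIPK10 was higher throughout (adjusted p = 0.000498, 0.00402 and 5.7e-05). The 8 genes were these, TCP5, AT4G01200 and AT3G33528 (higher) and AT1G15730 (lower).

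At 0 h, 16 of 21593 genes were called, 8 higher and 8 lower (657 at an unadjusted p under 0.05), among them AGL87 at 1.02 against 7.42 (adjusted p = 0.00128), the DNA demethylase gene DML1 at 23.2 against 36.9 (adjusted p = 0.00191) and U2.6, not assembled against 6.23 ± 5.81 (adjusted p = 0.0223). At 2 h, 12 were called, 9 higher and 3 lower (1067 at an unadjusted p under 0.05), with NUDT16 at 49.0 against 38.1 (adjusted p = 0.0288) and HMGB1, a chromatin protein gene, at 77.3 against 98.2 (adjusted p = 0.0203). The 2 h count was 7 without Col0 replicate 2 or 35S:TCP5 replicate 1 and 8 without Col0 replicate 3. Groups did not overlap for 8.60% of genes at 0 h and 9.85% at 2 h, where chance gives 10%.

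At 8 h, 27 genes were called, 10 higher and 17 lower, with 1200 at an unadjusted p under 0.05; in 16 of the 27 a group was not assembled. The protease gene DEG14 (chromosome 5, 9789468 to 9792299) rose to 20.6 ± 3.73 against 11.7 ± 0.87 (1.76-fold, adjusted p = 0.0143), SNOR111 stood at 3.68 with no piece in Col0 (adjusted p = 0.0306), and AGL87 at 1.28 against 5.06 (adjusted p = 0.0321). Not assembled in 35S:TCP5 were the abscisic acid receptor gene PYL2 (1.35 ± 0.65 in Col0, adjusted p = 0.0286), RALFL29 (1.73 ± 0.08, adjusted p = 8.77e-05), the pollen tube attractant gene LURE1.5 (2.31 ± 0.44, adjusted p = 0.0117) and LCR86 (2.08 ± 0.24, adjusted p = 0.0104). Groups did not overlap for 9.33% of genes, where chance gives 10%. The count was 13, 10 and 15 without Col0 replicates 1, 2 and 3, 9 with a piece in every library, and 51 with a replicate block within each time.

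The TCP relatives and ACS2 were not called between the genotypes at any time: ACS2 stood at 4.18 ± 4.92 FPKM in 35S:TCP5 and 5.84 ± 5.94 in Col0 at 8 h. Of 9 ethylene biosynthesis genes tested, 0 were called at 8 h, also adjusted over the list alone (list adjusted p = 0.426). At 0 h the tapetum and anther list alone differed, lower (adjusted p = 0.00469; adjusted p = 0.600 with an estimated correlation), with 0 of 9 called, also adjusted over the list alone. At 2 h ethylene perception and response and pollen markers were higher and epidermis and cuticle lower (adjusted p = 0.035, 0.0128 and 0.000195; adjusted p = 0.977 with an estimated correlation for each), with 0 of 19, 6 and 19 called, also adjusted over the list alone. At 8 h auxin response, cytokinin response, jasmonate and pollen lists were lower (adjusted p = 0.00332, 0.0395, 0.0214 and 0.0491; adjusted p = 0.482, 0.482, 0.511 and 0.625 with an estimated correlation). CIN-type TCP factors and cell cycle were higher (adjusted p = 0.0491 for both; adjusted p = 0.482 and 0.887 with an estimated correlation). None of the members was called, TCP5 aside, over all genes or adjusted over the list alone. TCP5 is the transgene, so the CIN-type TCP result in part restates the overexpression. With the replicate block the CIN-type TCP, cell cycle and pollen calls were lost (adjusted p = 0.0697 for each).

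The change over time differed between the genotypes in few genes. At 2 h 1 gene was called (687 at an unadjusted p under 0.05) and at 8 h 6 genes, 1 higher and 5 lower (966 at an unadjusted p under 0.05), with DEG14 and RALFL29 among them. Between 8 and 2 h 4 genes were called, all lower (499 at an unadjusted p under 0.05). The count at 2 h was 0 without Col0 replicate 1 or 2 at 0 h, Col0 replicate 3 at 2 h, 35S:TCP5 replicate 2 or 3 at 0 h, or 35S:TCP5 replicate 1 or 3 at 2 h. It was 2 without Col0 replicate 3 at 0 h, Col0 replicate 1 at 2 h or 35S:TCP5 replicate 2 at 2 h. The 8 h count was 0 without Col0 replicate 1 or 2 at 0 h, without any 1 Col0 library at 8 h, without 35S:TCP5 replicate 1 or 2 at 0 h, and without 35S:TCP5 replicate 2 or 3 at 8 h. It was 11 without Col0 replicate 3 at 0 h, 8 without 35S:TCP5 replicate 3 at 0 h and 3 without 35S:TCP5 replicate 1 at 8 h; voom called 0. With the replicate block, and with the block within each time, 0 genes were called in all 3 of these comparisons. The 8 against 2 h count was 0 without any 1 of Col0 replicates 2 and 3 and 35S:TCP5 replicates 1 and 3 at 2 h, any Col0 replicate at 8 h, or 35S:TCP5 replicates 2 and 3 at 8 h. The numbers of lists called were 2, 7 and 7 in these comparisons, none with an estimated correlation (lowest adjusted p = 0.677, 0.439 and 0.454 with an estimated correlation).

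The genes changed in pATML1:TCP5 petals were compared with 35S:TCP5 at 8 h. The 584 lower there were lower in inflorescences as a set (26.7% above 0 against 58.9% of all genes; camera p = 2.73e-13, and p = 0.123 with an estimated correlation). The 631 higher there were higher (p = 0.05, and p = 0.514 with an estimated correlation), and p = 0.0954 with median-of-ratios rescaling. TCP5 was the 1 gene called in the same direction in both. AT3G29644, chosen after its values were seen, was called in opposite directions. The set tests were not run with the replicate block, although same-numbered libraries at 8 h correlated at 0.27 to 0.80. They were not run at 0 h either, so whether the shift came before induction is not known.

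Col0 inflorescences themselves changed strongly over the same hours. At 2 h the calmodulin-like touch gene TCH3 rose 46.0-fold, to 349.6 ± 106 FPKM from 7.59 ± 0.97 (n = 3 and 3; adjusted p = 2.06e-06), and IGMT4 and PLA2A reached 42.5 ± 8.18 and 69.9 ± 29.5 with no piece at 0 h. HIR2 stood at 67.8 ± 10.1 against 0.206 (adjusted p = 2.61e-05). The morning clock gene LHY fell to 42.8 ± 1.26 from 154 ± 4.06 (adjusted p = 1.55e-06), and ESM1, SQP1 and cPT4 fell by 1.81, 2.16 and 2.33 on the log2 scale (adjusted p = 0.000903, 0.00043 and 0.000117). TCP13 rose to 8.64 ± 0.32 from 4.04 ± 0.63 (adjusted p = 0.0183).

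Among the groups at 2 h, early response genes for touch, wounding and cold rose (7 of 11 higher and 1 lower; 9 and 1 adjusted over the list alone; adjusted p = 5.93e-06; adjusted p = 0.0960 with an estimated correlation). Ethylene perception and response rose (13 of 19 higher, 16 adjusted over the list alone; adjusted p = 1.69e-09; adjusted p = 0.180 with an estimated correlation), with EBF2 at 70.3 ± 23.8 against 24.6 ± 1.52. Jasmonate genes rose (12 of 25 higher and 1 lower; 13 and 2 adjusted over the list alone; adjusted p = 1.21e-05; adjusted p = 0.180 with an estimated correlation). Flavonoid genes fell (11 of 13, also adjusted over the list alone; adjusted p = 1.89e-09; adjusted p = 0.0960 with an estimated correlation), and so did cell cycle genes (8 of 25, 10 adjusted over the list alone; adjusted p = 1.01e-05; adjusted p = 0.562 with an estimated correlation) and epidermis genes (8 of 19, also adjusted over the list alone; adjusted p = 0.00238; adjusted p = 0.427 with an estimated correlation). Senescence genes (3 of 9 higher) and clock genes (8 higher and 3 lower of 13) were higher, both also adjusted over the list alone (adjusted p = 0.0147 and 0.00439; adjusted p = 0.135 and 0.0960 with an estimated correlation). In all 4155 genes were called, 2487 higher and 1668 lower (7081 at an unadjusted p under 0.05), and 2716 without Col0 replicate 2 at 0 h or at 2 h.

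At 8 h the clock genes LHY, CCA1 and RVE8 had fallen by 5.79, 4.54 and 4.60 on the log2 scale (adjusted p = 7.37e-13, 1.45e-13 and 7.37e-13), LHY to 1.83 ± 0.42 FPKM. Of 27 photosynthesis genes 26 fell and 1 rose, also adjusted over the list alone (median −1.49, adjusted p = 1.23e-13; adjusted p = 0.393 with an estimated correlation). LHCB2.3, of light harvesting, stood at 12.7 ± 6.23 (log2 change −4.58, adjusted p = 4.84e-09). The glutathione transferase genes GSTF6, GSTF7 and GSTU9 stood at 331.5 ± 282, 301 ± 258 and 236 ± 192, against 2.52, 0.335 and no piece at 0 h, and ABCB4 at 227 ± 187 against 0.676. TCP17 fell to 1.82 ± 0.38 from 3.06 ± 0.21 (adjusted p = 0.0155). In all 7783 genes were called, 4165 higher and 3618 lower, with 10004 at an unadjusted p under 0.05.

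Falling lists at 8 h were epidermis and cuticle (13 of 19; adjusted p = 0.00041), auxin response (10 of 24, with 1 higher; adjusted p = 0.00207), flavonoid genes (9 of 13, with 1 higher; adjusted p = 0.000685), boundary and KNOX/BELL genes (6 of 12; adjusted p = 0.0144) and tapetum and anther markers (2 of 9; adjusted p = 0.0406), the counts being equal adjusted over the list alone. Cell cycle genes fell as well (4 of 25, 3 adjusted over the list alone; adjusted p = 0.00207). Rising lists were jasmonate (12 of 25, with 1 lower; 13 and 1 adjusted over the list alone; adjusted p = 0.00193), early response to touch, wounding and cold (8 of 11; adjusted p = 0.00207) and ethylene perception and response (7 of 19; adjusted p = 0.0221), the last pair with equal counts adjusted over the list alone. With an estimated correlation the adjusted p was 0.393 for these lists, except 0.601 for cell cycle and ethylene perception and response. All 13 clock genes were called, 7 higher and 6 lower, also adjusted over the list alone; the median was 0.97 and the mean −0.20 (list adjusted p = 0.366).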

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

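The tests of pollen, of clock genes against depth and TCP5 level, and of the line were chosen only after those results were seen; the splits, the time-of-day test and the iron test were written before their outcome was known. Weighing results starts with splits of the libraries. For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, so real value and highest other are given. For *tcp5* these were 48 and 1 genes (1 split as large, the real one) and 6 and 4 lists (1). For pATML1:TCP5 they were 1222 and 24 genes (1) and 7 and 7 lists (2). For 35S:TCP5 at 0 h they were 16 and 2 genes (1) and 1 and 7 lists (9), and at 2 h 12 and 2 genes (1) and 3 and 7 lists (9). At 8 h they were 27 and 2582 genes (2) and 6 and 4 lists (1). For Col0 they were 4155 and 1 genes (1) and 8 and 8 lists (4) at 2 h, and 7783 and 1 genes (1) and 10 and 9 lists (1) at 8 h.

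For the differences between times, genotype was regrouped within each time in 100 draws. At 2 h 42 draws called as many genes as the 1 found, at 8 h 8 draws as many as the 6 found, and between 8 and 2 h 26 draws as many as the 4 found. The highest draws called 185, 2511 and 2710 genes. Splits and draws that call many times the real count point to a structure among the 8 h samples other than genotype. It followed the replicate number in part: same-numbered 35S:TCP5 and Col0 libraries at 8 h correlated at 0.27 to 0.80. What a replicate number stands for is not given in the sources used here.

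The test of the difference between times picked out 7 genes whose change in 35S:TCP5 differed from that in Col0. At 2 h against 0 h it was AT1G51055 (log2 difference 0.87, adjusted p = 0.0163), at 3.79 and 2.04 FPKM in Col0 and 2.59 and 3.14 in 35S:TCP5. At 8 h against 0 h DEG14 differed by 1.1 (adjusted p = 0.0365), standing at 13.8, 12.1 and 11.7 FPKM at 0, 2 and 8 h in Col0 and at 10.6, 18.9 and 20.6 in 35S:TCP5. AT5G63820 differed by −1.1 (adjusted p = 0.0321), being unassembled at 0 h in Col0 alone. AT4G09465 (−1.67, adjusted p = 0.0161), AT4G31354 (−1.72, adjusted p = 0.0161), RALFL29 (−1.45, adjusted p = 0.0179) and AT5G34905 (−1.37, adjusted p = 0.0278) differed at 8 h against 0 h. These 4 differed by the same values at 8 h against 2 h, because they were assembled in Col0 at 8 h alone, at 1.58 to 2.32 FPKM, close to the assembly floor. With the replicate block, and with the block within each time, 0 genes were called at 8 h against 0 h, at 8 h against 2 h and at 2 h against 0 h. An effect of the induction on these genes was thus not shown.

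Pollen transcripts in *tcp5* petals were weighed first. The median pollen marker ranged over 3.44 log2 units among the 3 *tcp5* libraries, and the highest triple mutant library stood 0.54 above the controls although it lacked TCP5 as well. The tables thus argue against loss of TCP5 alone as the source, and pollen or anther material in replicates 1 and 3 may be the likelier one. The markers bear on the *tcp5* counts, with 1181 genes called without replicate 2. That count also rests on replicate 3, whose transcript coverage was low. Whether dissection or anther timing differed stays open.

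Clock genes in pATML1:TCP5 petals were weighed next; the overexpression controls stood apart at CCA1 (3.95 against 14.2 in the knockout controls), and pATML1:TCP5 at PRR9 and PRR5. Genes that fell in Col0 from 0 to 8 h stood 0.93 log2 units above those that rose. A difference in the time of day of collection could give this. In Col0, however, hour of day ran together with time after induction, over which touch and jasmonate genes also rose. The genes that rose may include such responses, so the difference cannot settle the hour of collection. Lower depth was argued against, since 6 of the 6 called clock genes were kept with voom and with genes assembled in every library. An effect of TCP5 level would turn these genes the other way in the triple mutant, yet they moved the same way by a median of 0.40, with a median SE of 0.26 and 0 called, which excludes little. Collection times are not given in the sources used here, so this stays open, and 248 genes were called without those that change with time in Col0.

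The genes shared by all 3 times in 35S:TCP5 were weighed last. Their log2 fold change at 8 h differed from that at 0 h by at most 0.31, TCP5 aside, and a fixed difference of the line may account for them. TCP5 was already high at 0 h, so a lasting effect of its transcript could do so too. The induction system is not given in the sources used here, so whether this transcript was active at 0 h is not known. Of the 6 genes among these 7 that were tested in petals, 0 were called in the same direction in pATML1:TCP5. That argues against an effect of the transcript only weakly, because petals and inflorescences differ. An uninduced sample of another line was not analysed here.

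The iron genes of the further observations gave a camera p = 0.800 at the preset correlation in the triple mutant, which cannot tell whether TCP5 level set the iron genes.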

How the results depend on the processing

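Named genes were compared in 2798 values under other settings: 2217 kept sign and call, 519 were weaker, 9 stronger and 53 reversed. List calls were compared in 360, of which 224 were kept, 135 weaker and 1 reversed. For none of the differences below was the cause tested; the cause was not tested either where a value reversed. Counts that moved by more than 1.5 times were these. For *tcp5* (48) there were 75 with a pseudocount of 0.1, 26 with the compared groups alone, 3 with the replicate block, 350 with array weights, 15 with voom, 263 with the length trend removed, 28 with a piece in every library and 3 with the pollen covariate. Leaving out 1 library gave 6 to 1181. For the triple mutant (115) there were 680 with the compared groups alone, 33 with the replicate block, 66 with the deposited FPKM, 76 with voom, 363 with the length trend removed and 200 with the pollen covariate, and 10 to 37 with 1 library left out. For the triple mutant against *tcp5* (6) there were 3 with a pseudocount of 0.1, 16 without the variance trend, 1 with the compared groups alone, 1 with the replicate block, 0 with voom, 29 with the length trend removed, 0 with a piece in every library and 2 with the pollen covariate, and 1 to 854 with 1 library left out. For pATML1:TCP5 (1222) there were 435 without the variance trend, 1948 with array weights, 237 with the deposited FPKM, 2086 with voom and 248 without genes called with time; the replicate block gave 925, and leaving out 1 library 380 to 813. For 35S:TCP5 at 0 h (16) array weights gave 120, the replicate block 14, the block within each time 22, and leaving out 1 library 12 to 15. At 2 h (12) there were 7 with the compared groups alone, 32 with array weights, 21 with the block within each time, 9 with the replicate block and 7 to 10 with 1 library left out. At 8 h (27) there were 13 with a pseudocount of 0.1, 11 with the compared groups alone, 2367 with array weights, 16 with voom, 9 with a piece in every library, 51 with the block within each time, 32 with the replicate block and 10 to 26 with 1 library left out. The inflorescence array weights did not converge (weight 31.6 for 1 Col0 library at 8 h), so those counts carry little.

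For the difference between 2 and 0 h (1) there were 3 with a pseudocount of 0.1, 3 without the variance trend, 0 with the compared groups alone, 0 with the replicate block, 7 with array weights, 0 with voom and 0 with the block within each time, and 0 to 2 with 1 library left out. For 8 against 0 h (6) there were 17 without the filter, 15 without the variance trend, 0 with the compared groups alone, 0 with the replicate block, 174 with array weights, 0 with voom, 0 with a piece in every library and 0 with the block within each time, and 0 to 11 with 1 library left out. For 8 against 2 h (4) there were 2 with a pseudocount of 0.1, 10 without the filter, 7 without the variance trend, 0 with the compared groups alone, 0 with the replicate block, 9 with array weights, 7 with the deposited FPKM, 0 with voom, 1 with the length trend removed, 0 with a piece in every library and 0 with the block within each time, and 0 to 3 with 1 library left out. Col0 at 2 h gave 8717 with array weights, 4570 with the replicate block and 2716 to 3364 with 1 library left out, and at 8 h 15170, 8095 and 5280 to 8889.

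Of 128 calls of named genes, 65 remained with the deposited FPKM, 84 with voom, 83 with a piece in every library and 89 with the replicate block. List calls numbered 72, and 0 with an estimated correlation and 43 with fry; fry kept 31 of the 72 in the same direction. Opposite calls between the triple mutant and pATML1:TCP5 (37) were 9 with the deposited FPKM and 13 without genes called with time. The gene shared by pATML1:TCP5 and 35S:TCP5 at 8 h (1) became 0 with the deposited FPKM and 2 with voom. The 40 calls shared by the mutants became 13 with voom and 24 with a piece in every library. The sets higher in pATML1:TCP5 were weaker with an estimated correlation in *tcp5* (p = 0.361), the triple mutant (p = 0.318) and 35S:TCP5 at 8 h (p = 0.514), and so was the lower set at 8 h (p = 0.123). The higher set at 8 h also had, at the preset correlation, p = 0.0789 with a pseudocount of 0.1, 0.0605 without the filter and 0.0954 with rescaling. Named calls kept when 1 library was left out were 3 to 13 of 13 in *tcp5*, 1 to 8 of 19 in the triple mutant, 24 to 33 of 45 in pATML1:TCP5 and 5 to 9 of 12 in 35S:TCP5 at 8 h.

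Reversed log2 values belonged to genes not called, except CYCA2;3 in pATML1:TCP5 (−0.26 with the deposited FPKM) and the flavonoid list between the mutants (fry adjusted p = 0.865). Ranges below are those with 1 library left out. TCP13 in *tcp5* was 0.20 with array weights, 0.35 with the deposited FPKM, 0.40 with the pollen covariate and −0.43 (without *tcp5* replicate 2) to 0.14 (without *tcp5* replicate 3). TCP17 in *tcp5* was −0.15 with the length trend removed and −0.22 (without control replicate 3) to 0.37, with −0.18 and −0.02 without *tcp5* replicates 1 and 2. With the deposited FPKM, TCP13 was 1.07 in the triple mutant and 0.72 against *tcp5*. In 35S:TCP5, TCP13 was −0.23 to 0.039 at 0 h (0.01 without Col0 replicate 3) and −0.50 to 0.074 at 8 h. ACS2 was −0.72 to 0.16 at 2 h (0.09 without Col0 replicate 3), and at 8 h 0.33 with voom and −1.41 to 0.56 (0.43 without Col0 replicate 3). TCP17 at 8 h was −0.19 with array weights and −0.028 to 0.19.

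Between 2 and 0 h, ACS2 was −0.72 to 0.16 with 1 library left out (reversed at 0.09 and 0.16). TCP5 there was 0.028 with the deposited FPKM and −0.21 to 0.17 with 1 library left out (reversed at 0.02, 0.03, 0.03, 0.04, 0.04, 0.08 and 0.17). Between 8 and 0 h, ACS2 was 0.26 with voom and −1.41 to 0.56 with 1 library left out (reversed at 0.43 and 0.56). TCP13 was −0.41 to 0.16 (reversed at 0.02, 0.03, 0.05 and 0.16), and TCP5 was −0.16 with the deposited FPKM. Between 8 and 2 h, ACS2 was 0.40 with a pseudocount of 0.1, 0.28 with the deposited FPKM, 1.27 with voom and −1.13 to 0.83 with 1 library left out (reversed at 0.09, 0.22, 0.23, 0.38, 0.71 and 0.83). There TCP13 was −0.15 to 0.42 (reversed at −0.15 and −0.07), TCP17 −0.10 with array weights and TCP5 −0.19 with the deposited FPKM. In Col0 at 8 h TCP5 was 0.27 with the deposited FPKM.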

Other observations

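Several iron deficiency genes, in no fixed list, had lower values in pATML1:TCP5 petals than in their controls, and the controls were the group that stood apart. Besides bHLH38, the regulators bHLH39 and bHLH101 had no piece in pATML1:TCP5 against 4.41 and 3.73 FPKM in controls. FRO3 stood at 25.5 against 56.3, OPT3 at 45.8 against 98.7, BTS at 11.8 against 22.2 and ORG1 at 20.5 against 60.5, while PYE was level at 32.3 against 33.6. The knockout controls were at 27.0 for FRO3, 43.7 for OPT3 and 19.8 for ORG1, close to pATML1:TCP5. A list of 10 such genes was chosen after these values were seen. A group test in that comparison would only restate the choice, so none is given.

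If TCP5 level set these genes, the list would be higher where TCP5 is lost. It was not called there (camera p = 0.845 in *tcp5* and p = 0.800 in the triple mutant, at the preset correlation). In the knockout experiment 5 of the 10 listed genes passed the filter, without bHLH38, bHLH39 and bHLH101, so the test excludes little. Iron supply or growth conditions that differed between the overexpression line and its controls may equally lie behind the change. Petals of both lines grown side by side and measured for iron would tell these apart.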
